A study of Plasmodium falciparum with 2 samples.

How the data were processed

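Chromatin immunoprecipitation with an antibody against MCM6 was performed on trophozoites of Plasmodium falciparum strain 3D7. Per the labels' protocols, chromatin was fixed with 1% formaldehyde for 10 min at 37 °C, sheared to about 500 bp, and sequenced as paired reads of 150 bases. The series labels give 2 samples, the MCM6 precipitate and the input, each with 1 library. The peak list of the MCM6 sample was the only processed file analysed. A serum control named in the protocol and the signal of the input library were not analysed here.

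Per the submitters' processing notes, the tools used were Bowtie2 2.3.4.1, SAMtools 1.7, Picard and MACS2 2.2.7.1. Their settings, the filters on reads, the use of the input as control and the genome build are not given in the sources used here. The deposited list has the 9 columns of a broad peak file. The authors' peak caller gives a fold enrichment (a linear ratio over background), a −log10 p and a −log10 q for each peak, each averaged over the peak in this format. The deposited score column equalled 10 times the −log10 q, cut to a whole number, in all 3813 lines. These values were used only to describe, rank or filter peaks within the list. No depth could be derived from it, so no counting interval was computed.

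Positions are given from 1 on the sequences named Pf3D7 v3 in the peak list. Genes came from a RefSeq table of assembly GCF_000002765.6 with 5615 nuclear genes. It gives locus tags and spans but neither strand, exons nor products, and no symbol differed from the locus tag, so genes are named by locus tag. Whether the table and the peak list share coordinates was checked by shifting the peaks by up to 5 kb in steps of 50 bp. The percent of peak bases in genes was highest with no shift on 14 of 14 chromosomes, and within 50 bp of no shift in 28 of 28 parts when each chromosome was divided at its middle. Chromosome extents run to the last gene or peak, since chromosome lengths were not used here.

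Results, tests, alternatives and the rule for named genes were fixed before the data were examined. Base composition, sequence motifs, read uniqueness, coding exons, gene starts and ends and lists by product name were planned but not run, as they need a genome sequence, strand, exons or product names. Midpoints in gene spans took the place of midpoints in coding exons, and the relation of fold enrichment to width was kept without base composition. Of the fixed gene lists, those by gene class could be made (rRNA, tRNA, and snRNA with snoRNA). Peak edges near gene edges, gene length classes, chromosome-end stretches and the test of genes near chromosome ends were added after the data were seen. So were the lists of other ncRNA, pseudogenes and protein-coding genes. The rule named the 10 nuclear peaks of highest fold enrichment, the 5 widest and the 5 protein-coding genes with the most covered bases. It also named up to 3 members of each fixed list, and this part was later applied to the lists of other ncRNA and pseudogenes. Its part on the MCM and origin recognition complex genes was not run, as it needs product names.

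The share of midpoints, edges or bases in genes was tested against 10000 rotations, in which all peaks of a chromosome shift by 1 random offset. Chromosome-end shares were tested against 10000 random placements within the chromosome, and peak spacing against 1000. Numbers per chromosome were tested against 10000 random assignments by length. Gene lists were tested as the number of genes with at least 1 bp under a peak against 10000 random lists matched on length decile, with Benjamini-Hochberg adjustment over 3 fixed and, separately, 3 added lists. Correlations used 100000 permutations. All tests were two-sided with a threshold of 0.05.

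The tests were checked on simulated data. With no planted effect, the rotation test passed its threshold in 4.5% of 200 simulated lists of 3807 peaks and the list test in 5.0% of 600 tests over 5615 genes. The correlation test passed in 7.5% of 200 simulations of 500 values, the spacing test in 2% of 100 simulated lists, the chromosome-end test in 5% of 100 and the test per chromosome in 4.82% of 2800 tests, each on 3807 peaks apart from the correlation. When 70%, 80% and 90% of midpoints were planted in genes, 70.2%, 80.7% and 89.7% were recovered. A list of 200 genes with a planted ratio of 1.5 gave 1.46 and passed, while a ratio of 1.2 gave 1.11 and did not. The list check does not show how the test behaves for lists whose genes share peaks, such as the rRNA genes. The correlation check used far more values than there are chromosomes. It therefore does not cover the relation of peak density to chromosome length.

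Alternatives were stricter peak thresholds, other overlap and end distances, merging of peaks within 500 bp, the middle 500 bp of each peak, other random arrangements and the exclusion of 100 kb at each chromosome end. Computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.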

Results

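The association of MCM6, a subunit of the helicase that unwinds DNA during replication, with the genome of the malaria parasite Plasmodium falciparum was measured by chromatin immunoprecipitation and sequencing. The parasites were of strain 3D7, the reference strain of the species, and were at the trophozoite stage, when DNA replication begins within the red blood cell. The series held 2 libraries, 1 from chromatin precipitated with an antibody raised against MCM6 and 1 from input chromatin, with no replicate of either. The data analysed were the peaks that the authors called for the MCM6 library. The peak list holds no read counts, so the depth of either library is unknown. Every p-value below describes the arrangement of this peak list against random arrangements and carries no information on the spread between cultures.

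The MCM6 peaks were numerous, broad and of low enrichment. The list held 3813 peaks, of which 3807 lay on the 14 nuclear chromosomes, 5 on the apicoplast genome and 1 on the mitochondrial genome. The nuclear peaks covered 8.24 Mb, or 35.5% of the 23.2 Mb that the chromosomes span from position 1 to the last gene or peak. Their median width was 1417 bp, with a range of 257 to 28779 bp, and 54 of them were wider than 10 kb. The authors' fold enrichment over background had a median of 1.28 among nuclear peaks, with quartiles of 1.22 and 1.36. It reached 1.5 in 250 nuclear peaks (6.57%) and 2 in 3 of them. The −log10 q, which the peak caller averages over a broad peak, had a median of 2.65. It was below 1.3 in 649 nuclear peaks (17.0%) and at least 5 in 665 (17.5%).

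**Figure D1:**
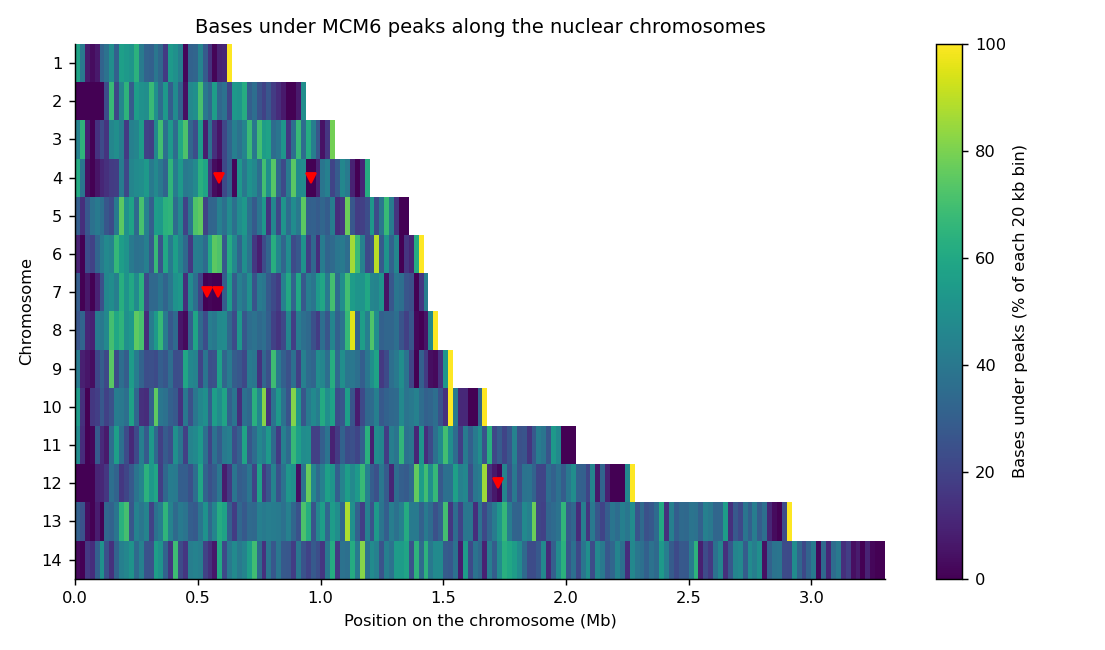
Percent of bases under MCM6 peaks in 20 kb bins along each of the 14 nuclear chromosomes, with position in Mb on the horizontal axis, chromosome number on the vertical axis and the color giving the percent. Red triangles mark the 5 internal stretches of at least 30 kb without a peak, which lay on chromosomes 4, 7 and 12, and the dark bins near the chromosome ends are the parts poor in peaks.

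MCM6 peaks lay almost entirely within genes. The midpoints of 96.3% of the 3807 nuclear peaks fell inside an annotated gene, against a mean of 60.2% (SD 0.77) when the peaks of each chromosome were shifted together by random offsets, and 3166 peaks (83.2%) lay wholly inside genes. Of the nuclear peaks, 3427 overlapped 1 gene, 313 overlapped 2 genes and 30 overlapped at least 3 genes. Only 37 overlapped no gene, and 33 of these were within 100 kb of a chromosome end. The difference from the 10000 rotations was larger than any of them gave (two-sided permutation p = 0.0002, the smallest the rotations can give). Counted by bases, 93.7% of the peak sequence was in genes, and the percent for single chromosomes ranged from 81.7% on chromosome 1 to 97.4% on chromosome 14. The gene spans do not separate exons from introns, so no share in coding sequence was computed.

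Peak edges lay close to gene edges more often than those of rotated peaks. Rotation does not keep peaks inside genes, so part of this excess may come with the placement of peaks in genes. Of the 7614 peak edges, 21.8% lay within 100 bp of a gene edge, against a mean of 9.64% (SD 0.33) for rotated peaks (two-sided permutation p = 0.0002). Among protein-coding genes more than 100 kb from a chromosome end, 0.736% of the positions 1000 bp outside the gene, and in no other gene, were under a peak. The percent rose to 7.87% at 150 bp outside, 15.5% at 50 bp inside and 45.7% at 250 bp inside, and it levelled off near 71.2% at 1500 bp inside. Positions far inside exist only in long genes, with 9642 edges at 50 bp and 2620 at 1500 bp. The 1310 genes long enough for every distance gave 15.2% at 50 bp, 46.7% at 250 bp and 71.2% at 1500 bp inside. Intergenic stretches held few peak bases, with 3.00% of their bases covered and 87.7% of the 5563 stretches untouched. Stretches of up to 0.5 kb were bridged from end to end in 25% of 668 cases, and those of 0.5 to 1 kb in 13.1% of 1471. Only 9 of the 1994 stretches of 1 to 2 kb and 0 of the 1430 longer than 2 kb were bridged. No neighbouring peaks lay closer together than 1029 bp. Whether the peak caller joined peaks across shorter gaps is not given in the sources used here, and such joining would add to the bridged stretches of up to 1 kb and to the peak widths.

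**Figure D2:**
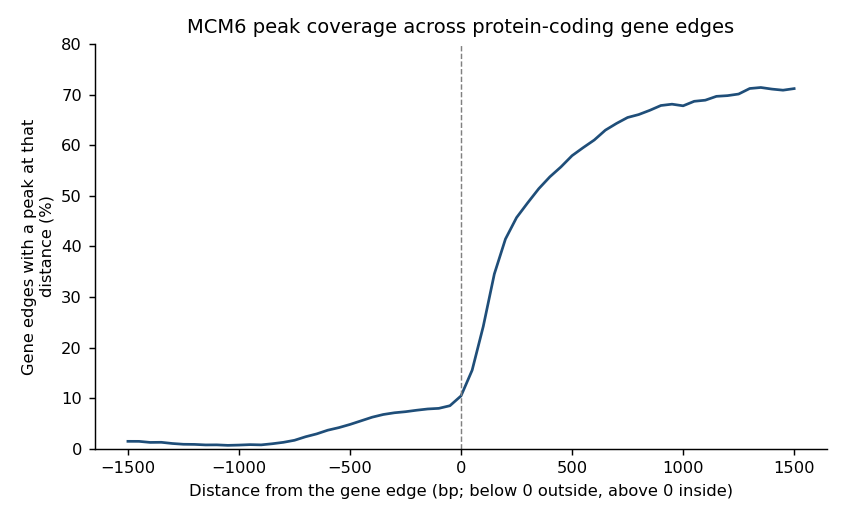
Percent of protein-coding gene edges with an MCM6 peak at each distance from the edge, in 50 bp steps, with negative distances outside the gene and positive distances inside, for genes more than 100 kb from a chromosome end. The line rises from 0.736% at 1000 bp outside to 45.7% at 250 bp inside and 71.2% at 1500 bp inside.

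Of the 10 peaks of highest fold enrichment, 9 overlapped a protein-coding gene, and their widths ran from 522 to 2465 bp, with 4 of them wider than the nuclear median. The highest was on chromosome 12 at 526651 to 527777, inside PF3D7_1211800, with a fold enrichment of 2.04 and a −log10 q of 35.7. The peak on chromosome 4 at 235211 to 236140, inside PF3D7_0404300, reached 2.03-fold, and that on chromosome 14 at 1673482 to 1674003, inside PF3D7_1441100, reached 2.02-fold. PF3D7_1357000 on chromosome 13 held a peak of 1.98-fold at 2265857 to 2267060. Both PF3D7_1035900 and PF3D7_1035200 on chromosome 10 were among the 10 highest, with 1.84-fold and 1.81-fold peaks at 1424197 to 1425615 and 1394815 to 1396679. PF3D7_1224300 on chromosome 12 (988684 to 991148, 1.84-fold) and PF3D7_0608800 on chromosome 6 (362705 to 363784, 1.83-fold) completed the genes of this group outside chromosome 7. On chromosome 7, PF3D7_0725300 held a 1.92-fold peak at 1072085 to 1074212. The neighbouring peak at 1080703 to 1081895, of 1.98-fold, overlapped no gene and lay 647 bp from PF3D7_0725400. It was the only peak of the 10 highest outside genes. These positions were ranked by the authors' own values, and with 1 library no error can be given for them.

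The widest peaks ran through long protein-coding genes or lay at chromosome ends. The widest peak, on chromosome 6 at 1124782 to 1153560, spanned 28.8 kb inside PF3D7_0628100 at 1.29-fold. Peaks of 28.2 kb inside PF3D7_1038400 (chromosome 10, 1519451 to 1547676, 1.31-fold) and 25.6 kb inside PF3D7_0826100 (chromosome 8, 1113507 to 1139083, 1.32-fold) followed. The other 2 of the 5 widest overlapped no gene and were the outermost peaks at the right ends of chromosomes 10 and 9, at 1654398 to 1678632 and 1510033 to 1532794. By bases covered, PF3D7_0628100 came highest with 29.7 kb (96.3% of the gene) under 2 peaks. PF3D7_0511500 on chromosome 5 had 28.4 kb covered (94.2%) by 2 peaks, and PF3D7_0522400 on chromosome 5 had 23.0 kb (80.9%) covered by 3. A single peak covered 28.2 kb (98.0%) of PF3D7_1038400, and another covered 25.6 kb (99.2%) of PF3D7_0826100.

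Fold enrichment and width were weakly related across the nuclear peaks, which are not independent replicates. Pearson's r was 0.084 and Spearman's rho was 0.17 (permutation p = 1e-05 for each, the smallest the draws can give). Among the 665 peaks with a −log10 q of at least 5 the relation ran the other way, with a rho of -0.31. Among the 3158 peaks with a −log10 q of at least 1.3, rho was 0.0067 and did not pass the test. The q value is computed from the same signal as the fold enrichment and averaged over the peak, so these filters select on the quantities compared, and the change of sign is not a separate finding about MCM6.

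**Figure D3:**
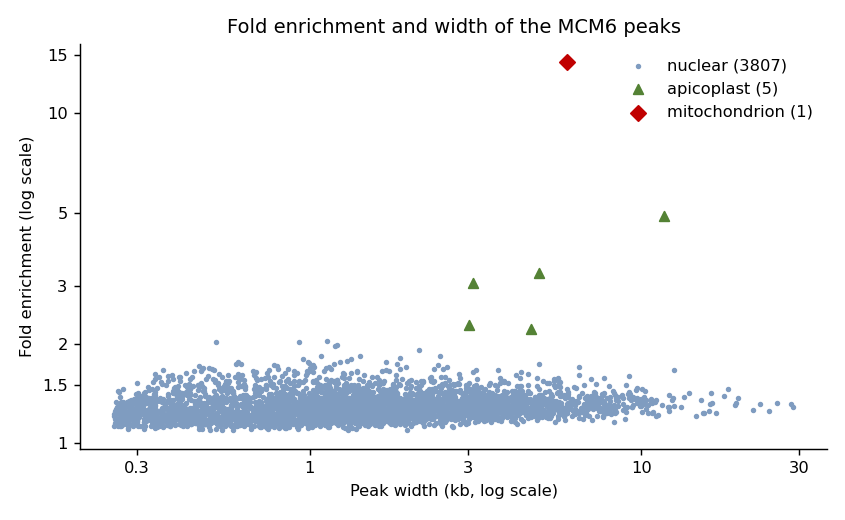
Fold enrichment against width in kb, both on log scales, for the 3807 nuclear peaks (points), the 5 apicoplast peaks (triangles) and the 1 mitochondrial peak (diamond). Nuclear peaks stay between 1.09-fold and 2.04-fold at every width, below all the organelle peaks.

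Long protein-coding genes carried MCM6 peaks more often, and the shortest less often, than rotated peaks gave. Rotated peaks lay in genes less often than the called peaks, so an excess among longer genes partly restates that placement. Of the 5282 protein-coding genes, 3642 (69.0%) overlapped a peak and 697 (13.2%) were covered over at least 90% of their span. Among genes of up to 0.5 kb, 22.9% of 271 had a peak, fewer than the 41.3% for rotated peaks. Genes of 1 to 2 kb had peaks in 64.6% against 58.4%, those of 2 to 4 kb in 82.9% against 72.6%, and those of 4 to 8 kb in 94.0% against 85.2%. Each of these differences passed the rotation test (permutation test, Benjamini-Hochberg adjusted p = 0.0003 over 6 length classes). Genes over 8 kb had peaks in 97.2% against 93.0% (permutation test, adjusted p = 0.0156), where the rotated value left little room for an excess. Genes of 0.5 to 1 kb did not differ detectably, with 46.7% against 48.3% (permutation test, adjusted p = 0.342).

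**Figure D4:**
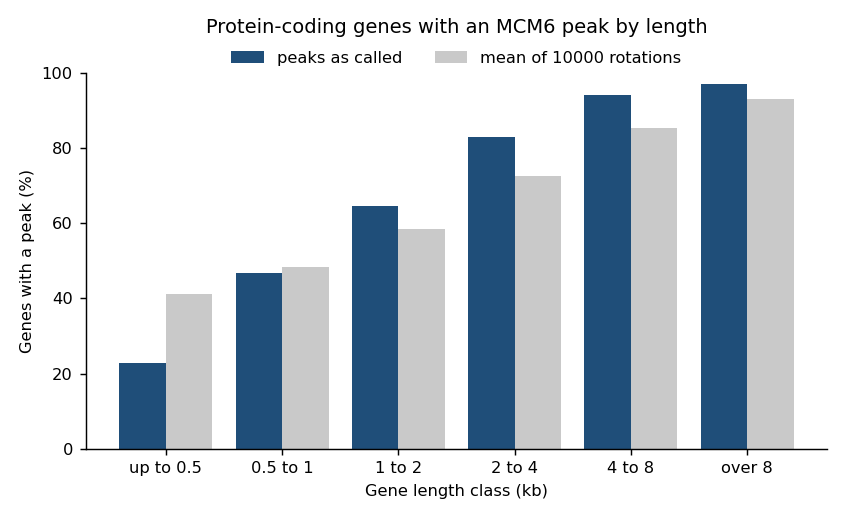
Percent of protein-coding genes with at least 1 bp under an MCM6 peak, by gene length class in kb; dark bars show the peaks as called and grey bars the mean of 10000 rotations. Genes of up to 0.5 kb lie below the rotated value (22.9% against 41.3%) and genes of 2 to 4 kb above it (82.9% against 72.6%).

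Genes for tRNAs were free of MCM6 peaks and few snRNA and snoRNA genes carried them, while the result for ribosomal RNA genes varied with the comparison. None of the 45 tRNA genes overlapped a peak, where random lists matched on gene length gave a mean of 10.1 (permutation test, adjusted p = 0.0006). Their count stayed at 0 with peaks of −log10 q of at least 5 and with the top 10% by fold, but only 2.27 and 1.79 genes were expected there and the test was not passed (permutation test, adjusted p = 0.261 and 0.45). With 1 kb added on either side, 10 of the 45 tRNA genes had a peak against 19.8, still a deficit (permutation test, adjusted p = 0.0039). Of the 47 snRNA and snoRNA genes, 3 had a peak against 10.8 in matched lists (permutation test, adjusted p = 0.0066). These were PF3D7_0626840 (1.51-fold peak, chromosome 6), PF3D7_0804100 (1.32-fold, chromosome 8) and PF3D7_1109700 (1.20-fold, chromosome 11). With 1 kb added on either side, 23 of the 47 genes had a peak against 20.8, in the other direction (permutation test, adjusted p = 0.609). The deficit did not pass with peaks of −log10 q of at least 5, the higher-fold part, the top 10% by fold or the middle 500 bp of peaks, where the ratios were 0.417, 0.348, 0.524 and 0.366 with 1.91 to 5.74 genes expected. Of the 28 rRNA genes, 19 had a peak against 14.1 (permutation test, adjusted p = 0.032). These tests drew 10000 lists each, and their p-values were adjusted over the 3 lists fixed beforehand. Matching by decile does not equalize lengths within the shortest decile, and stretches between genes held few peak bases. The tests therefore cannot tell whether the tRNA, snRNA and snoRNA deficits belong to these classes or to short genes outside longer ones. The result for rRNA genes did not hold against rotated peaks, which gave 15.4 genes (permutation test, adjusted p = 0.41). With the peaks of −log10 q of at least 5 the excess was larger, 11 genes against 2.54 (ratio 4.32), as it was with the top 10% by fold, 10 against 1.36 (ratio 7.33, permutation test, adjusted p = 0.0006 for each). Without the 100 kb at each chromosome end, 12 of 21 rRNA genes had a peak against 10.8, and that difference did not pass either (permutation test, adjusted p = 0.697). Of the 19 genes, 10 lay under 2 peaks, 1 each on chromosomes 5 and 7, so the genes of this list are not independent. The 10 genes of the top 10% by fold were these same genes, so that excess rests on 2 peaks. The random lists drew genes singly, so the p-values for rRNA genes overstate the evidence.

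The rRNA genes differed between chromosomes. All 5 on chromosome 5 and all 5 on chromosome 7 were covered over at least 95% of their span, by peaks of up to 1.61-fold and 1.7-fold. PF3D7_0725600, PF3D7_0725700 and PF3D7_0725800 lay under the same chromosome 7 peak, at 1083837 to 1090330. Elsewhere, peaks overlapped 2 of 5 rRNA genes on chromosome 1, 4 of 4 on chromosome 8 and 1 of 3 on chromosome 11. They overlapped 2 of 3 on chromosome 13 and 0 of 3 on chromosome 14. The gene table names no products, so differences between kinds of rRNA gene could not be separated from differences between chromosomes. Copies of these genes resemble each other in sequence, so reads cannot always be assigned to a single copy and the values per gene are uncertain.

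Peaks lay on all 14 nuclear chromosomes, and their number per Mb was higher on the longer ones. By number, the densest were chromosomes 13 and 14, with 181 and 176 peaks per Mb, and the sparsest were chromosomes 1 and 2, with 139 and 142. The share of bases under peaks had another order, highest on chromosome 6 at 39.4%. Chromosomes 13 and 14 had 36.7% and 34.0%, and chromosomes 1 and 2 had 34.1% and 32.3%. Chromosome 13 had 528 peaks against 478 for random placement, a ratio of 1.10 and the only chromosome with an unadjusted p under the threshold (permutation p = 0.023). No chromosome passed after adjustment over the 14 chromosomes, and chromosome 13 had an adjusted p of 0.305. By covered bases, the ratio for chromosome 13 was 1.03. Across the 14 chromosomes, peaks per Mb rose with length, with a Pearson's r of 0.80 (permutation p = 0.0005) and a Spearman's rho of 0.81 (permutation p = 0.00069), a test added after the data were seen. Without chromosomes 13 and 14, the farthest from the median length, r was 0.67 (permutation p = 0.018). Without the 100 kb at each chromosome end, r was 0.71 over all 14 (permutation p = 0.00422) and 0.50 without chromosomes 13 and 14 (permutation p = 0.102). The peaks with a −log10 q of at least 5 did not show the relation, with a rho of -0.24 (permutation p = 0.408). The median fold enrichment per chromosome stayed between 1.26 on chromosome 9 and 1.29 on chromosome 7.

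The outer parts of the chromosomes were poor in peaks. Peak midpoints within 100 kb of a chromosome end made up 6.02% of the 3807, against 11.8% (SD 0.38) when peaks were placed at random within their chromosome (two-sided permutation p = 0.0002). Of the 460 protein-coding genes in these parts, 163 (35.4%) overlapped a peak, while 3479 of the 4822 elsewhere (72.1%) did. Lists of genes matched on length gave a mean of 281 genes with a peak, a ratio of 0.58 (permutation p = 0.0002). This comparison was added after the data were seen and partly restates the deficit of midpoints. Its random lists drew genes singly, while neighbouring genes near an end share peaks and peak-free stretches, so its p-value overstates the evidence. The bases of these genes were covered to 25.3%, against 58.5% elsewhere. Pseudogenes, a list added after the data were seen, had peaks in 37 of 158 cases against 86.8 in matched lists, a ratio of 0.43 (permutation test, adjusted p = 0.0002). Only 48 of them lay outside these end parts. There the deficit was weaker, with 21 against 33.5, a ratio of 0.63 (permutation test, adjusted p = 0.0002). The random lists for pseudogenes also drew genes singly, so the same limit applies to them.

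**Figure D5:**
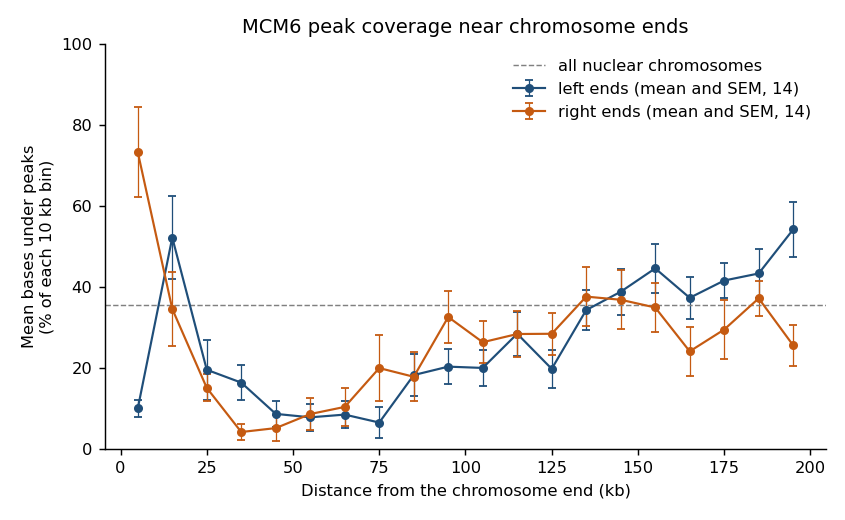
Mean percent of bases under MCM6 peaks in 10 kb bins against the distance from the chromosome end in kb, for the 14 left and the 14 right ends, with the standard error over ends; the dashed line is the 35.5% of all nuclear chromosomes. Right ends are measured from the last peak or gene, which is a peak at 11 of them, and the mean falls to 4.14% at 30 to 40 kb from right ends and to 6.48% at 70 to 80 kb from left ends.

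A band of peaks at the extreme ends preceded the peak-poor part. Peaks lay beyond the outermost protein-coding gene at 21 of the 28 ends, where they covered a median of 11.8 kb (5.25 to 24.2 kb) at a mean fold enrichment of 1.16 to 1.33 per end. At 12 of the 14 left ends the outermost peak started between positions 7263 and 11864. The left end of chromosome 2 instead held no peak over its first 129.8 kb, which contain 25 genes from PF3D7_0200100 to PF3D7_0202500. The left end of chromosome 12 held none over 90.4 kb and 12 genes from PF3D7_1200100 to PF3D7_1201100. Among right ends, that of chromosome 11 was peak-free for 62.1 kb, that of chromosome 14 for 48.1 kb and that of chromosome 5 for 29.1 kb. The stretches named here were chosen after their values were seen.

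Long stretches without a peak also occurred inside chromosomes 4, 7 and 12. There were 5 of at least 30 kb more than 100 kb from an end, where random placement gave a mean of 0.7 and reached 5 in 1 of 1000 placements (permutation p = 0.004). The longest, on chromosome 7 at 556967 to 609611, measured 52.6 kb and held 8 genes from PF3D7_0712500 to PF3D7_0713200. It was longer than the longest stretch in any of 1000 random placements, which reached 50.5 kb at most (permutation p = 0.002, the smallest they can give). Another stretch of chromosome 7 lay beside it at 519707 to 556703. Chromosome 4 held stretches at 933841 to 986464 and 562816 to 612272, and chromosome 12 held 1 at 1702890 to 1739638. These stretches were also chosen after the data were seen.

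How the distance between neighbouring peaks compared with chance depended on the random placements and on the peaks used. The median distance was 2688 bp, with quartiles of 1677 and 4374 bp, against a mean of 2706 bp for the medians of 1000 random placements (permutation p = 0.711). Those placements allow neighbours closer than 1029 bp, which the peak list does not contain. Placements that kept at least that distance, a test added after the data were seen, gave a mean of 3020 bp, and the observed median was shorter (permutation p = 0.002). Without the 100 kb at each chromosome end the median was 2655 bp against 2450 bp (permutation p = 0.002), which reversed the direction. These placements again allowed neighbours closer than 1029 bp, which by itself lowers the random median. Leaving out the ends and keeping the minimum distance together was not run, so the reversal cannot be assigned to the ends. Among the 665 peaks with a −log10 q of at least 5, the median distance of 19865 bp was shorter than the 21850 bp of random placement (permutation p = 0.018).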

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

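All tests in this part were chosen after the results were seen.

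Enrichment on the organelle genomes stood outside the nuclear comparisons and exceeded every nuclear peak. A single peak covered the mitochondrial sequence from position 2 to 5967 at a fold enrichment of 14.3, which was 11.1 times the nuclear median. The apicoplast, a plastid with its own genome, held 5 peaks over 80.1% of the sequence up to position 34197. Its highest, at 22503 to 34197, reached 4.89-fold, and its lowest, at 16450 to 21083, was 2.22-fold.

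A candidate technical explanation is that organelle DNA made up a larger part of the MCM6 library than of the input library, which would raise the whole organelle genome alike. Whether the input served as the peak caller's control is not given, and without it the folds would not compare the 2 libraries. The apicoplast folds were not level, with a highest over lowest ratio of 2.21, but the peak caller's local background can also make them vary. This explanation therefore cannot be told apart from binding in the organelles, because the peak list holds no coverage of either library. No biological explanation was tested, as no other group of samples has peaks here.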

How the results depend on the processing

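The stricter threshold of −log10 q of 1.3, the distances of 50 and 200 bp for peak edges, the exclusion of the left ends of chromosomes 2 and 12, all alternatives for peak edges and added gene lists, random placements with a minimum gap and the relation of peak density to chromosome length were chosen after the results were seen. Merging peaks within 500 bp joined none, so its 14 values are left out. Of the other 121 alternative values, 88 kept their direction and side of the threshold (for counts, stayed within 1.5 times), 15 lost the threshold, 5 gained it, 5 reversed and 8 counts moved further. The excess of midpoints in genes, the excess of peak edges near gene edges and the deficit near chromosome ends held in every alternative run, and no chromosome passed in any. The number of peaks fell from 3813 to 671 at a −log10 q of at least 5, to 1907 in the higher-fold part, to 382 in the top 10% and to 9 at 2-fold. That last setting left 3 nuclear peaks and was not tested further. Of the 3 fixed gene lists, 3 passed in the main analysis but 1 did at a −log10 q of at least 5, in the higher-fold part, in the top 10% and with the middle 500 bp of peaks, where fewer or shorter peaks leave fewer genes with a peak. The list that passed was rRNA at a −log10 q of at least 5 (ratio 4.32) and in the top 10% (7.33), and tRNA in the other settings. In the top 10%, the rRNA genes with a peak lay under only 2 peaks. The rRNA ratio of 1.35 turned to 0.759 with the middle 500 bp and lost the threshold in 5 further alternatives, with ratios of 1.03 to 1.63. With 1 kb added on either side of genes, the snRNA and snoRNA ratio of 0.279 turned to 1.10, and the cause was not tested. The deficit of other ncRNA genes lost the threshold at a −log10 q of at least 5 (ratio 0.216) and in the top 10% (0 genes). Median peak spacing relative to random placement moved from 0.993 to 0.909 at a −log10 q of at least 5, 0.843 in the higher-fold part, 0.852 in the top 10%, 0.946 at 1.3 and 0.89 with random gaps of at least 1029 bp, each past the threshold. It reversed to 1.08 without the chromosome ends, where random placements again allowed gaps under 1029 bp, and the cause was not tested. Spearman's rho of fold enrichment and width moved from 0.17 to -0.31 at a −log10 q of at least 5 and to 0.0067 at 1.3, filters that select on a value tied to fold. The rho of peaks per Mb and chromosome length, 0.81, turned to -0.24 at a −log10 q of at least 5 and was 0.57 at 1.3 and 0.71 without the chromosome ends. Alternatives that need a genome sequence were not run, and leaving out a replicate was not possible with 1 library per group. The unknown depth limits what the absence of a peak shows.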

Other observations

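All tests in this part were chosen after the results were seen, except the rotation of peaks against genes.

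Genes of other noncoding RNAs also carried few peaks, in 10 of 55 cases against 22.3 in lists matched on length (permutation test, adjusted p = 0.0002 over the 3 added lists). The difference did not pass with the peaks of −log10 q of at least 5 (1 gene against 4.63) or the top 10% by fold (0 against 3.06). PF3D7_0829900 on chromosome 8 had the highest fold among them, with a 1.40-fold peak at 1275942 to 1280145 over 90.0% of the gene, followed by PF3D7_0804200 on chromosome 8 at 1.32-fold and PF3D7_1148200 on chromosome 11 at 1.31-fold. The pseudogenes with the highest folds were PF3D7_0400200 on chromosome 4 (1.66-fold), PF3D7_1353000 on chromosome 13 (1.54-fold) and PF3D7_0902700 on chromosome 9 (1.37-fold). Away from the chromosome ends, only 4 peaks overlapped no gene. Besides the 1.98-fold peak on chromosome 7, they were at 2791158 to 2791575 on chromosome 13 (1.28-fold), 1355971 to 1356292 on chromosome 8 (1.27-fold) and 462338 to 462626 on chromosome 6 (1.21-fold).

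The placement of peaks inside genes exceeded chance, since the highest of 10000 rotations put 66.3% of midpoints in genes against 96.3% observed. A candidate technical explanation is base composition, since coding sequence of this parasite is less rich in A and T than the sequence between genes, and shearing and amplification could recover it unevenly in the precipitate and the input. Composition was not measured here. Protein-coding genes near chromosome ends had peaks 0.58 times as often as genes of their length, so coding for a protein did not alone give a gene a peak, but their composition may differ too. Base composition and MCM6 occupancy of genes cannot be told apart without the genome sequence or the input signal, and no biological explanation was tested.

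The peak-poor ends and internal stretches may mark clusters of variant surface antigen gene families, which in this species lie near chromosome ends and also inside some chromosomes. These were taken here as chromosomes 4, 7, 8 and 12, a set that may be incomplete and that the gene table, which names no families, could not check. Of the 10 longest internal stretches, 7 fell on these chromosomes (none on chromosome 8), as in a share of 0.007 of 1000 random placements. Of the 7, those at 109124 to 132217 and 146547 to 169286 on chromosome 4 lay close to the 100 kb end part, and the other 3 stretches lay on chromosomes 9, 6 and 14. Without peaks narrower than 500 bp, which split neighbouring stretches on chromosome 7, 5 of 10 did (a share of 0.11). With the same filter, the shares for the 5, 8 and 20 longest stretches were 0.026, 0.039 and 0.009, so the result depended on the number taken. The stretches tested are those that prompted the explanation and the clusters were not located, so it stays open. A technical alternative, reads shared between copies of such genes, stays open, since peaks were present beyond the outermost gene at 21 of 28 chromosome ends, but which of these lie in repeated sequence was not measured. For the left ends of chromosomes 2 and 12, loss of the end in the cultured line is a further candidate explanation, because 129.8 kb and 90.4 kb there lacked any peak, where the other 12 left ends had a peak starting within 12 kb; the right ends of chromosomes 5, 11 and 14 were also peak-free over shorter stretches, and without the input signal, it cannot be told apart from low occupancy.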
